A study of Danio rerio with 6 samples.

How the data were processed

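Polyadenylated RNA was measured by RNA sequencing in 6 samples of zebrafish cells, 3 labelled control and 3 labelled as treated with a morpholino against znf711. A morpholino is an antisense oligonucleotide, given to embryos, that blocks the translation or the splicing of its target transcript. The cells carried the Tg(mpx:eGFP) reporter, in which green fluorescent protein marks cells that use the mpx promoter, and the labels call them neutrophils enriched as GFP-positive cells at 48 hours post-fertilisation. Groups and replicate numbers came from the sample titles. The series' design text speaks of a znf711 mutant line in place of a morpholino, and the grouping here followed the sample labels. What the control embryos received is not given in the sources used here.

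The authors deposited 1 table per sample with raw read counts per gene, per the file headers. Each table has 59330 rows, of which 32520 are Ensembl genes and 26810 are unnamed gene models. The submitters' processing notes list Trimmomatic, HISAT2 2.0.5, HTSeq, edgeR and DESeq2 1.16.1 without a role or an order, and the build GRCz11. The annotation release, the use of strand and the treatment of reads with several positions are not given in the sources used here. Reads of near-identical copies, overlapping genes and antisense pairs may therefore be split or lost, and counts of such genes are uncertain. The deposited tables also hold FPKM values, per the file headers. These were used in a check alone: between 50.5% and 64.1% of the counted rows had an FPKM equal, within a tolerance of 0.001, to the count divided by the listed length and the table's total. Some of the symbols in the tables read as dates, and none of these genes is named here. Of the Ensembl identifiers, 29201 also stood in the reference table of gene names.

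Counts as deposited were tested with edgeR 4.0.16 under R 4.3.3. Rows were kept by filterByExpr with its minimum count of 10, scaled by TMM, and fitted with the robust quasi-likelihood model with the group as the only term. P-values were adjusted by Benjamini-Hochberg over all rows tested, with a threshold of 0.05, and a second count also asked for a 2-fold difference. Levels are TMM-scaled CPM, counts scaled to a common library total, except that a sum over a list is in CPM of all counts without TMM. Errors of levels are SD over 3 libraries. Errors of log2 fold changes are approximate standard errors, the absolute log2 fold change divided by the square root of the edgeR F statistic. All log2 fold changes compare the morpholino group with the control group. A count of 0 allows up to 3 counts, which comes to between 0.248 and 1.84 CPM in the 6 libraries, and such limits cover counting error only.

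A total of 38 gene lists, for neutrophil functions, other cell types and general cell processes, was fixed before the data were examined. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Fisher's exact test, two-sided, compared called genes on each chromosome with those on the others. Of the list entries, 28 had no matching gene in the tables.

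The genes named in the text followed a rule also fixed before the data were examined. It took znf711 and phf8, a fixed set of neutrophil and progenitor genes, the genes past the threshold or, with fewer than 10 of these, the 10 genes of smallest unadjusted p with a symbol, fixed morpholino-response genes, and the most abundant member of each list of other cell types. Some genes that the rule takes are not reported here. Any other gene is said to have been chosen after its values were seen.

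Alternatives comprised DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other filters on low counts, leaving out each library in turn, a replicate block, and the removal of mitochondrial, haemoglobin and ribosomal protein genes. Further runs without the libraries of lowest mpx level, and with library weights, were added after the data were examined. The code was tested on simulated data drawn from the means, library sizes and dispersions of this comparison, with 200 changed genes. These were taken only from rows above a minimum mean level and outside the gene lists, so the recovery does not cover rows of lower level. The 37 genes of the proteasome list were also changed 2-fold, and calls among them were not counted as false. With the dispersion of these libraries, edgeR recovered 64 of 100 genes changed 16-fold and 8 of 100 genes changed 4-fold, with 5 false calls among 14596 rows. DESeq2 recovered 83 and 15 of them, with 97 false calls among 16637 rows. With a coefficient of variation of 0.2, edgeR recovered 100 of 100 genes at either fold among 16453 rows.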

Results

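The comparison asked how loss of Znf711, a zinc finger transcription factor studied here with the histone demethylase Phf8, alters gene expression in zebrafish neutrophils. Libraries from GFP-positive cells of Tg(mpx:eGFP) zebrafish at 48 hours post-fertilisation comprised 3 controls and 3 from the znf711 morpholino group, labelled as biological replicates. Total counts were 7181804, 9311439 and 7635673 in control replicates 1 to 3. In morpholino replicates 1 to 3 they were 1629804, 12093109 and 9550796. Morpholino replicate 1 was the shallowest library and had counts in 8041 Ensembl genes, against 13434 to 16074 in the other 5 libraries. The first principal component of the log2 levels held 54.8% of the variance and set this library apart from the other 5. Spearman correlations across genes, which are not independent replicates, ranged from 0.680 to 0.780 among controls, from 0.532 to 0.798 among morpholino libraries and from 0.567 to 0.857 between the groups.

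**Figure D1:**
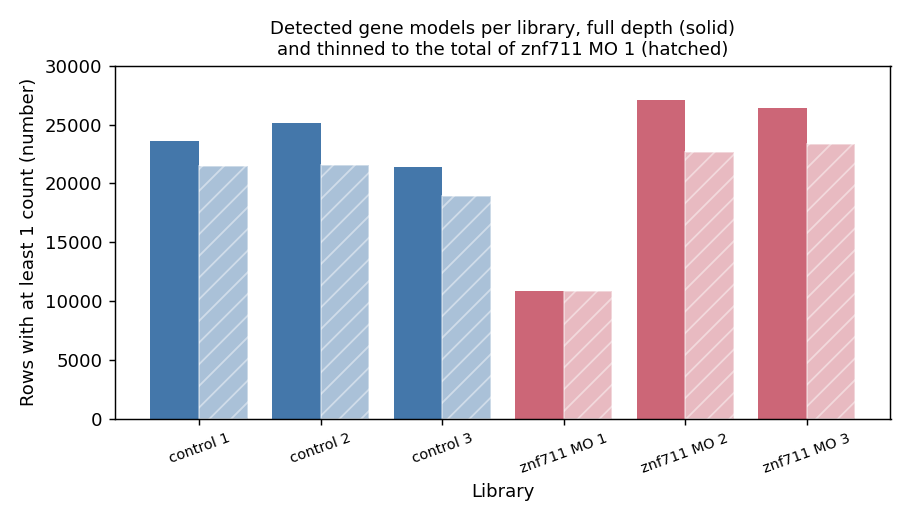
Number of gene models with at least 1 count in each library (vertical axis), at full depth (solid bars) and as the mean of 20 random draws at the total of morpholino replicate 1 (hatched bars). Morpholino replicate 1 had counts in 10821 models, and the other 5 libraries in 21374 to 27127 at full depth.

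The targeted gene znf711 (ENSDARG00000071868, GRCz11 chromosome 14, 11975344 to 12020653, minus strand) was measured at 22.5 ± 16.5 CPM in controls and 9.82 ± 8.65 CPM in the morpholino group (SD, n = 3 each). Its raw counts were 348, 134 and 60 in the controls and 1, 120 and 182 in morpholino replicates 1 to 3. The log2 fold change was -1.17 ± 1.29, with an edgeR adjusted p of 0.9999, and morpholino replicates 2 and 3 lay within the control range. A morpholino need not lower the amount of its target transcript, so these counts do not check the labels. Without morpholino replicate 1 the log2 fold change was -0.66, and without control replicate 1 it was -0.41. The partner gene phf8 (ENSDARG00000006584, chromosome 23, 27591366 to 27608257) was at 44.0 ± 24.0 CPM in controls and 48.2 ± 4.96 CPM in the morpholino group, a log2 fold change of 0.13 ± 0.66. The 33 measured genes of histone lysine demethylases and their partners had a median log2 fold change of -0.13, and the list did not pass (camera adjusted p = 0.566).

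The neutrophil genes mpx, csf3r, spi1b, cebpa and cebp1 had counts in all 6 libraries, and none passed between the groups. The myeloperoxidase gene mpx (ENSDARG00000019521), whose promoter drives the reporter, was at 520, 2926 and 2703 CPM in control replicates 1 to 3 and at 559, 2731 and 5068 CPM in morpholino replicates 1 to 3. Its log2 fold change was 0.44 ± 0.79. The receptor gene of granulocyte colony-stimulating factor, csf3r, was at 15.3 ± 3.78 CPM in controls and 47.7 ± 51.3 CPM in the morpholino group, where replicate 3 alone reached 107 CPM. The transcription factor genes spi1b, cebpa and cebp1 had log2 fold changes of 0.14 ± 0.52, 0.05 ± 0.65 and 0.26 ± 1.19. The progenitor regulators runx1, with 0 counts in morpholino replicate 1, and myb had log2 fold changes of 0.15 ± 1.66 and -0.28 ± 0.62. The edgeR adjusted p was 0.9999 for each of these genes. The nuclear factor gene gfi1aa had 3, 0 and 38 counts in controls and 0, 11 and 26 in the morpholino group, too few to be tested.

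The lysozyme gene lyz (ENSDARG00000057789, chromosome 24, 24035863 to 24038800), an abundant neutrophil transcript, had 1, 1 and 4 counts in controls and 0, 8 and 2 in the morpholino group and was not tested. An unnamed gene model of 605 bases, at 24036188 to 24039118 of an alternate scaffold of chromosome 24, lay at the matching position of lyz, whose listed length was 603 bases. This model had 2717, 42082 and 19853 counts in control replicates 1 to 3 and 34, 67650 and 10382 in morpholino replicates 1 to 3.

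No gene passed the threshold between the groups. Of 16637 rows tested by edgeR, 12471 of them Ensembl genes, 0 were higher and 0 lower in the morpholino group, with or without the 2-fold limit, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 174 rows, 97 higher and 77 lower, where 832 would be reached by chance with uniform p-values. DESeq2 called 140 rows, 112 higher and 28 lower, and limma-voom called 0. The common biological coefficient of variation was 1.09. The groups did not overlap for 1238 rows, or 7.44%, where chance gives 10%.

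The 10 named genes of smallest unadjusted p were mostly near zero in one group, and none of them passed in edgeR with all 6 libraries. The striated muscle myosin gene myhz2 was at 0.987 ± 0.60 CPM in controls and 24.6 ± 8.84 CPM in the morpholino group, a log2 fold change of 4.61 ± 1.5. The homeobox gene irx4b had 2, 0 and 0 counts in controls and 115, 69 and 54 in the morpholino group. The disintegrin family gene adam11 and the gene FP102961.1 had 0 counts in each control library. They had 53, 42 and 35 counts, and 92, 43 and 25 counts, in morpholino replicates 1 to 3. The metalloprotease gene adam17b had 0, 0 and 1 counts in controls and 71, 15 and 46 in the morpholino group. In the other direction, the cardiac transcription factor gene tbx20 had 116, 21 and 66 counts in controls and 0 in each morpholino library. The receptor gene tnfrsf18 had 27, 52 and 107 counts in controls and 0 in each morpholino library. The tetraspanin gene cd81b had 155, 69 and 104 counts against 0, 1 and 1, the gene zgc:136930 had 48, 150 and 32 against 0, 1 and 0, and BX537263.5 had 22, 263 and 654 against 0, 13 and 7. Without control replicate 1, BX537263.5 passed in edgeR (log2 fold change -6.54, adjusted p = 0.0162). DESeq2 called each of these 10 genes. Across all rows, 29 had at least 10 counts in all 3 libraries of one group and 0 in the other 3 libraries, and in the other ways to divide the 6 libraries into 3 and 3 there were 34 to 172 such rows.

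Of the gene lists, 12 of the 35 tested passed camera, 7 higher and 5 lower in the morpholino group. None passed with an estimated correlation, where the smallest adjusted p was 0.433, and none passed with fry. In data simulated with the dispersion of these libraries, a list of 37 genes changed 2-fold had a camera adjusted p of 3.31e-09. That simulated list did not pass with an estimated correlation either (adjusted p = 0.291). The simulation was drawn from means, library sizes and dispersions, with no correlation between genes set. In it 0 other lists passed, whereas 4 to 22 lists passed camera in the other equal divisions of the real libraries. It therefore does not show how either correlation setting performs on correlated genes. In the real data no member of any list passed over all genes or when adjusted over the list alone. The lists of p53 targets, connective tissue and endothelium kept their call and direction without each library in turn. The other 9 lists lost the call or turned in at least 1 of those fits.

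Target genes of the p53 response, which morpholinos are known to induce, were higher as a list in the morpholino group (camera adjusted p = 0.000153; adjusted p = 0.433 with an estimated correlation). Of 23 measured members 17 had a positive fold change, the median log2 fold change was 0.32, and 0 passed, over all genes and adjusted over the list alone. The cell cycle inhibitor gene cdkn1a was at 2.97 ± 2.17 CPM in controls and 31.7 ± 16.4 CPM in the morpholino group, a log2 fold change of 3.40 ± 1.28. The ubiquitin ligase gene mdm2 was at 8.23 ± 9.53 and 31.2 ± 12.0 CPM. Among members chosen after their values were seen, rps27l was at 16.7 ± 2.57 and 69.4 ± 21.5 CPM, and ccng1 at 126 ± 111 and 285 ± 33.8 CPM. In 5 members every morpholino library lay above every control library and in 0 members below, where chance gives 1.15 each way. None of these genes passed in edgeR, with an adjusted p of 0.9999. The interferon response, also known to follow morpholino injection, did not pass (camera adjusted p = 0.452), isg15 was at 7.19 ± 6.16 and 3.83 ± 3.48 CPM, and rsad2 had 0 counts in every library. The apoptosis list did not pass either (camera adjusted p = 0.134), but was higher without control replicate 2 (adjusted p = 0.0360) or morpholino replicate 1 (adjusted p = 0.0445).

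**Figure D2:**
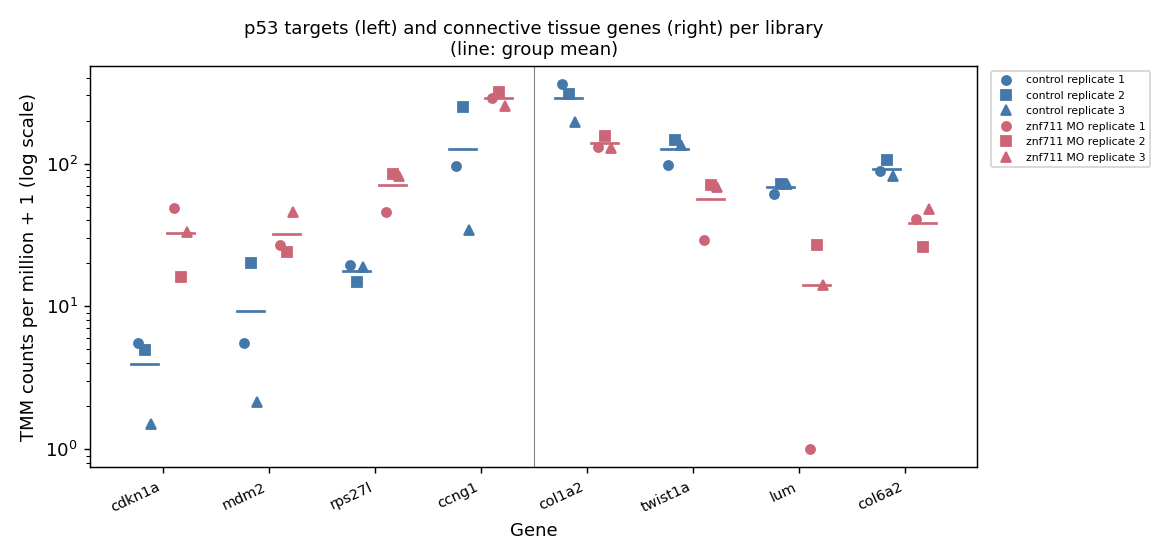
TMM-scaled CPM plus 1 (log axis) of 4 genes of the p53 list and 4 connective tissue genes in the 6 libraries, with lines at the mean of each group of 3. The morpholino libraries lie above all controls for cdkn1a, mdm2, rps27l and ccng1, and lie below all controls for col1a2, twist1a, lum and col6a2.

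Connective tissue genes were lower as a list in the morpholino group (camera adjusted p = 0.000438; adjusted p = 0.788 with an estimated correlation). Of 29 measured members 23 had a negative fold change, with a median of -0.63 on the log2 scale. In 9 members every morpholino library lay below every control library and in 1 member above, where chance gives 1.45 each way. The collagen gene col1a2 was at 287 ± 84.4 CPM in controls and 138 ± 14.9 CPM in the morpholino group, a log2 fold change of -1.06 ± 0.45. Chosen after their values were seen, the proteoglycan gene lum was at 67.2 ± 6.11 and 13 ± 12.9 CPM and the mesenchymal factor gene twist1a at 125 ± 25.7 and 55.3 ± 23.7 CPM. The collagen gene col6a2, chosen in the same way, was at 91.3 ± 12 and 37.3 ± 11.4 CPM. The endothelial list was also lower (camera adjusted p = 0.000985; adjusted p = 0.788 with an estimated correlation), with 18 of 22 members negative and a median of -0.80. Its most abundant member, the water channel gene aqp1a.1, was at 120 ± 41.1 and 81.5 ± 42.2 CPM. The summed levels of these lists were 2133 ± 747 and 1440 ± 43.7 CPM for connective tissue and 687 ± 67.0 and 440.5 ± 131 CPM for endothelium. Of the 38 lists, these 2 alone had sums that did not overlap between the groups, where chance gives 3.8.

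Lists of mature neutrophil and macrophage functions were higher by camera, and their calls changed when single libraries were left out. Neutrophil effector genes had 15 of 23 members positive and a median log2 fold change of 0.40 (camera adjusted p = 0.000153; adjusted p = 0.910 with an estimated correlation). Without control replicate 1 the direction turned (camera adjusted p = 0.379). The summed level of the list was 3155, 15123 and 16816 CPM in control replicates 1 to 3 and 4685, 15539 and 28308 CPM in morpholino replicates 1 to 3. All 6 measured genes of the phagocyte NADPH oxidase were positive, with a median of 0.67 (camera adjusted p = 0.00823; adjusted p = 0.910 with an estimated correlation). That call was lost without control replicate 1 (adjusted p = 0.313) and without morpholino replicate 3 (adjusted p = 0.196). Inflammation genes had a median of 0.40 (camera adjusted p = 0.0109; adjusted p = 0.910 with an estimated correlation), and the direction turned without control replicate 1 (adjusted p = 0.517) or morpholino replicate 3 (adjusted p = 0.564). Chosen after its values were seen, the cytokine gene il1b was at 393, 969.5 and 2709 CPM in controls and at 158, 1433 and 5629 CPM in the morpholino group. Lysosomal genes had a median of 0.16 (camera adjusted p = 0.000331; adjusted p = 0.910 with an estimated correlation), and the call was lost without control replicate 1 (adjusted p = 0.893) or morpholino replicate 3 (adjusted p = 0.0649). Macrophage markers passed as higher (camera adjusted p = 0.0192; adjusted p = 0.910 with an estimated correlation) although their mean log2 fold change was -0.06 and their median 0.25. Their direction turned without control replicate 1 (adjusted p = 0.904), and the call was lost without morpholino replicate 2 (adjusted p = 0.338) or 3 (adjusted p = 0.0807), or without a filter on low counts (adjusted p = 0.277). The macrophage marker MFAP4 was at 669 ± 585 and 945 ± 584 CPM. Leaving out control replicate 1 alone keeps morpholino replicate 1, the other library of low neutrophil level. Without both of them, a run chosen after the data were examined, each of these lists stayed higher in direction. NADPH oxidase (camera adjusted p = 0.00701), inflammation (0.0180) and lysosomal genes (0.00701) passed there. Neutrophil effector genes and macrophage markers did not (0.140 each).

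**Figure D3:**
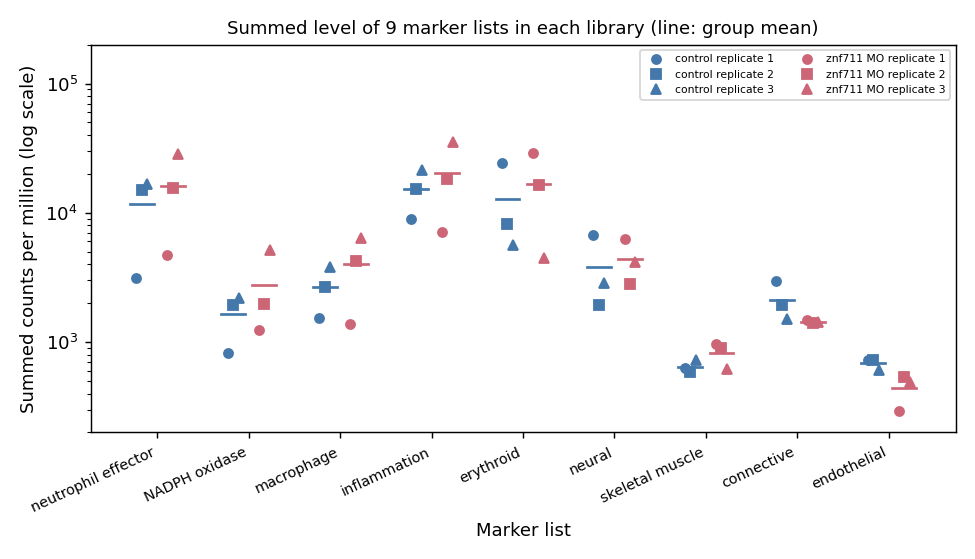
Summed CPM (log axis) of 9 marker lists in the 6 libraries, with lines at the mean of each group of 3. Neutrophil effector genes were lowest in control replicate 1 and morpholino replicate 1, the libraries in which erythroid genes were highest at 24328 and 29279 CPM.

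Ribosomal protein, progenitor and lymphoid lists were lower. Cytosolic ribosomal protein genes had 71 of 78 members negative and a median log2 fold change of -0.30 (camera adjusted p = 5.98e-09; adjusted p = 0.910 with an estimated correlation). Their summed level was 109858, 81342 and 47274 CPM in morpholino replicates 1 to 3 and 79844 to 94782 CPM in controls, and the direction turned without morpholino replicate 3 (adjusted p = 0.196). Haematopoietic progenitor genes had 14 of 18 members negative and a median of -0.48 (camera adjusted p = 0.0180; adjusted p = 0.788 with an estimated correlation). Chosen after its values were seen, the blood lineage factor gene tal1 was at 67.3 ± 8.14 CPM in controls and 37.9 ± 5.39 CPM in the morpholino group. The progenitor call was lost without control replicate 2 (adjusted p = 0.0821), control replicate 3 (adjusted p = 0.0785) or morpholino replicate 2 (adjusted p = 0.423). All 8 measured lymphoid genes were negative, with a median of -1.03 (camera adjusted p = 0.0220; adjusted p = 0.788 with an estimated correlation). The lymphoid call was lost without control replicate 2 (adjusted p = 0.0594) or 3 (adjusted p = 0.0879), and without morpholino replicate 1 (adjusted p = 0.0740), 2 (adjusted p = 0.0713) or 3 (adjusted p = 0.101). It was also lost with the stricter filter (adjusted p = 0.343) and without a filter on low counts (adjusted p = 0.102). The chemokine receptor gene ccr9a, its most abundant member, was at 181 ± 109 and 170 ± 140 CPM.

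Erythroid and neural genes had counts in every library. Erythroid genes summed to 24328, 8212 and 5653 CPM in control replicates 1 to 3 and 29279, 16544 and 4512 CPM in morpholino replicates 1 to 3. Neural genes summed to 6692, 1919 and 2843 CPM and to 6311, 2805 and 4170 CPM. Neither list passed (camera adjusted p = 0.975 and 0.470). Erythroid genes passed as higher without control replicate 1 (adjusted p = 0.0194) or morpholino replicate 3 (adjusted p = 7.84e-11), and as lower without control replicate 3 (adjusted p = 0.0394), without morpholino replicate 2 (adjusted p = 0.0102) or without a filter on low counts (adjusted p = 0.0124). Neural genes passed as higher without control replicate 1 (adjusted p = 0.00762), and as lower without control replicate 2 (adjusted p = 6.60e-06), without morpholino replicate 1 (adjusted p = 0.00842) or without that filter (adjusted p = 0.0199). The haemoglobin gene hbae3 was at 5659 ± 4229 and 7870 ± 6436 CPM and the neural gene marcksl1b at 1445 ± 304 and 1676 ± 894 CPM. Skeletal muscle genes passed as higher (camera adjusted p = 0.0220; adjusted p = 0.788 with an estimated correlation), with 14 of 25 members positive and a median log2 fold change of 0.11. That call was lost without control replicate 2 (adjusted p = 0.521), morpholino replicate 1 (adjusted p = 0.102) or morpholino replicate 2 (adjusted p = 0.201), and also with ranks (adjusted p = 0.0772) or without a filter on low counts (adjusted p = 0.254). The enolase gene eno3, the most abundant member and also on the glycolysis list, was at 359 ± 200 and 338 ± 146 CPM. The thrombocyte, epidermis, hatching gland, liver and yolk, and pigment lists did not pass, with camera adjusted p of 0.736, 0.577, 0.975, 0.208 and 0.953, and the epidermis list passed as higher without morpholino replicate 3 (adjusted p = 0.000702). Their most abundant members f5, cfl1l, xbp1, rbp4 and tspan36 had log2 fold changes of -0.01 ± 1.21, 0.16 ± 0.84, -0.37 ± 0.45, 0.42 ± 0.99 and -0.02 ± 0.69. Of these genes, cfl1l is also on the neutrophil effector list and xbp1 on the list of the unfolded protein response. The mast cell and eosinophil, lens and pancreas lists had fewer than 5 measured members. The mast cell gene cpa5, also on the neutrophil effector list, was at 922 ± 708 and 795 ± 492 CPM. The lens gene crybb1l2 was at 4.19 ± 4.62 and 23.3 ± 31.4 CPM.

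The remaining lists did not pass in the fit of all 6 libraries with filterByExpr and the group as the only term. The camera adjusted p was 0.0797 for dissociation stress, 0.106 for glycolysis, 0.184 for mitosis, 0.470 for DNA replication, 0.311 for the mitochondrial ribosome, 0.401 for the tricarboxylic acid cycle and 0.452 for oxidative phosphorylation. It was 0.401 for myeloid regulators, 0.470 for each of the proteasome, ribosome biogenesis and the unfolded protein response, 0.682 for splicing and 0.669 for haem and iron handling. The direction of the camera test was opposite to the sign of the median fold change for the interferon, glycolysis, unfolded protein response, haem and iron, erythroid and hatching gland lists. Dissociation stress genes passed as lower without control replicate 1 (adjusted p = 0.000237) or 3 (adjusted p = 0.000148), without morpholino replicate 2 (adjusted p = 2.93e-08) or 3 (adjusted p = 0.0471) and with the stricter filter (adjusted p = 0.0324), and turned without control replicate 2 (adjusted p = 0.862). Without morpholino replicate 3, oxidative phosphorylation (adjusted p = 3.09e-07), proteasome (adjusted p = 0.000268), mitosis (adjusted p = 0.00122), glycolysis (adjusted p = 0.0301) and ribosome biogenesis (adjusted p = 0.0471) passed as higher. Glycolysis also passed as higher without control replicate 2 (adjusted p = 0.0147) or 3 (adjusted p = 0.0176), the unfolded protein response without control replicate 2 (adjusted p = 0.0212) and oxidative phosphorylation without control replicate 3 (adjusted p = 0.0313). The mitochondrial ribosome passed as lower without morpholino replicate 1 (adjusted p = 0.0141) or 2 (adjusted p = 0.0327), and ribosome biogenesis without morpholino replicate 2 (adjusted p = 0.0300). Without a filter on low counts, DNA replication (adjusted p = 0.00565), the mitochondrial ribosome (adjusted p = 0.00403), ribosome biogenesis (adjusted p = 0.00511) and splicing (adjusted p = 0.0110) passed as lower. Heat shock genes took 4.63%, 9.59% and 2.31% of counts in control replicates 1 to 3 and 2.43%, 5.08% and 1.93% in morpholino replicates 1 to 3. Mitochondrial genes took 20.5% in control replicate 3 and 4.37% to 10.1% in the other 5 libraries.

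By chromosome, 0 of the chromosomes passed Fisher's exact test, since edgeR called no gene. With the genes at an unadjusted p under 0.05 in place of called genes, chromosome 14, which carries znf711, had 5 of 483 genes, or 1.04%, against 0.991% on the other chromosomes (exact test, adjusted p = 0.971). The smallest adjusted p was 0.472, for chromosomes 3 and 16.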

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

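The runs without 2 libraries, DESeq2 without morpholino replicate 1, and the library weights were chosen after the data were examined. The edgeR and limma-voom counts of called genes were 0, and so were those past the 2-fold limit, under every scaling, the stricter filter, the removal of abundant genes, library weights, and without control replicate 1 and morpholino replicate 1 together. Without a low count filter 2 genes were called, and DESeq2 called 140, each at least 2-fold. DESeq2 without morpholino replicate 1 called 155. Leaving out each library in turn gave 0 to 2 calls, 1 without control replicate 1 and 2 without morpholino replicate 3, the same 2 unnamed gene models as without a low count filter. Deviations of same-numbered libraries correlated at 0.135, 0.112 and 0.014, against -0.136 to 0.0746 for libraries with different numbers. The last of the same-numbered values lay under a limit of 0.1, so the numbers were not taken to pair the samples. Some levels, such as summed erythroid, neural and neutrophil effector genes and the heat shock share, took the same order over replicates 1 to 3 in both groups. Others, such as cytosolic ribosomal proteins and the mitochondrial share, did not. Control replicate 2 and morpholino replicate 2 had the highest Spearman correlation of any pair, at 0.857, while the replicates numbered 3 reached 0.731. A pairing is therefore not excluded, and the fits without the block do not allow for one. With the replicate block 0 genes were called and 14 lists passed, with 11 of the 12 calls kept in direction (lymphoid adjusted p = 0.0625) and 3 lists gained, dissociation stress as lower (adjusted p = 2.36e-06) and erythroid genes and mitosis as higher (adjusted p = 0.0438 each). Lists past the threshold numbered 0 with an estimated correlation and 0 with fry, and 10 to 14 without each library in turn. Camera without control replicate 1 and morpholino replicate 1 gave 10 lists, with 8 of the 12 calls kept in direction. The fold change of znf711 stayed negative in every setting, from -1.87 to -0.41 without each library in turn, and did not pass. Of 37 named genes tested, 16 changed direction in at least 1 setting, none of them called by edgeR, and the cause was not tested. DESeq2 gave log2 fold changes of 0.017 for f5 and 0.013 for tspan36. Limma-voom gave -0.59 for runx1, 0.69 for f5, 0.065 for ccr9a, 0.40 for cpa5, 0.14 for eno3, -0.38 for rbp4 and 0.33 for tspan36. Size factors of DESeq2 in edgeR gave 0.017 for f5 and 0.013 for tspan36. Library size alone gave 0.20 for f5, 0.074 for ccr9a, 0.012 for cpa5, 0.10 for eno3 and 0.20 for tspan36. The replicate block gave -0.25 for cebpa, -0.77 for runx1, 0.15 for cpa5 and 0.035 for eno3. Without each library in turn the log2 fold change ranged from -0.49 to 0.47 for ccr9a, -0.23 to 1.35 for cebp1, -0.61 to 0.55 for cebpa, -0.60 to 0.94 for cfl1l, -0.74 to 0.23 for cpa5, -0.57 to 0.31 for eno3, -0.55 to 0.55 for f5, -0.30 to 1.27 for hbae3, -1.54 to 0.015 for isg15 and -0.31 to 0.45 for marcksl1b. It ranged from -0.31 to 0.92 for mpx, -0.17 to 0.65 for phf8, -0.75 to 1.07 for rbp4, -1.10 to 0.71 for runx1, -0.22 to 0.54 for spi1b and -0.69 to 0.66 for tspan36. The camera adjusted p ranged from 1.09e-27 to 0.196 for cytosolic ribosomal proteins, 1.27e-07 to 0.564 for inflammation, 6.01e-05 to 0.904 for macrophage markers and 2.41e-15 to 0.379 for neutrophil effector genes, each of which turned in direction. The alternative for normalised units was not run, since the tables hold counts. Morpholino replicate 1 was the shallowest library, where a count of 0 allows up to 1.84 CPM by counting error alone. Its depth was not its only limit, since the other libraries thinned to its total had counts in at least 18896 rows, against 10821.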

Other observations

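The tests of single libraries, the splits counted for genes, chromosomes, lists and the p53 list, and the tests of morpholino replicate 1 in the higher and the lower DESeq2 calls were chosen after the results were seen or could be deduced in part.

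The genes of this paragraph were chosen after their values were seen, and none passed in edgeR. The helix-loop-helix gene id2a was at 179.5 ± 45.0 CPM in controls and 94.95 ± 22.2 CPM in the morpholino group (SD, n = 3 each), and cebpd at 371 ± 151 and 210 ± 44.6 CPM. The homeobox gene meis1b, of the progenitor list, was at 159 ± 101 and 81.0 ± 13.8 CPM. Of the 31 measured myeloid regulators, id2a, cebpd and tal1 were lower in every morpholino library than in every control. These were 3 members, against 0 that were higher, where chance gives 1.55 each way. The list as a whole went the other way, with 18 members positive and a median log2 fold change of 0.15, and did not pass (camera adjusted p = 0.401). The groups overlapped for csf3a, il6 and ncf1. The cytokine gene csf3a was at 11.9, 6.39 and 34.4 CPM in controls and at 0.537, 33.4 and 268 CPM in morpholino replicates 1 to 3. In morpholino replicate 3 il6, at 194 CPM, and ncf1, at 3266 CPM, were also higher than in the other 5 libraries.

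Some genes had fewer counts than a model on an alternate scaffold, a comparison chosen after the counts of lyz were seen. Of 142 Ensembl genes with a gene model on an alternate scaffold at the matching position, on the same strand and within 5% of the length, 50 had at least 10 times fewer counts than that model, and 20 had at least 10 times more, with at least 100 counts on the higher side. The 50 genes share 44 models, since some models overlap several genes, and include lyz, with 16 counts over all libraries against 142718, and 4 of them, lyz among these, belong to the fixed lists. The model beside lyz was at 378, 4519 and 2600 CPM in control replicates 1 to 3 and at 20.9, 5594 and 1087 CPM in morpholino replicates 1 to 3, and was lowest in the libraries with the lowest mpx.

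By camera with the preset correlation, the p53 target list was higher in the morpholino group. It did not pass with an estimated correlation (camera adjusted p = 0.433). The difference may reflect chance, the knockdown, a response to the oligonucleotide itself, or the samples' composition. Dependence on 1 morpholino library is argued against, since without each of them the list stayed higher with a camera adjusted p of at most 0.0014. With the neutrophil level of each library as a covariate the mean log2 fold change of the voom values was 0.768, against 0.782 without it, with 17 of 23 members positive and a camera adjusted p of 0.00047 and an SD over members of 1.21. The covariate was the summed neutrophil effector list, in which lyz had only 16 counts over all libraries. Its sums were 11698 ± 7447 CPM in controls and 16177 ± 11825 CPM in the morpholino group and overlapped, so it could remove little of a group difference. It covers the neutrophil level alone, so composition stays open. The summed connective tissue (2133 and 1440 CPM) and endothelial (687 and 440.5 CPM) markers did not overlap between the groups. Only these 2 of 38 lists did so, where chance gives 3.8, so their separation does not show a difference in composition. The camera adjusted p with an estimated correlation, 0.783, had already missed the threshold without the covariate, at 0.433, and decides nothing. Of the 10 splits of the libraries into 3 and 3, 1 split, the real one, gave an adjusted p as small as 0.000153, the smallest of the others being 0.0269, and 10 splits are too few for a share under 0.05; an effect of the oligonucleotide was not tested against the loss of Znf711.

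DESeq2 called 140 rows where edgeR called 0, and a candidate explanation is that single sparse libraries carry these calls. Of the 112 higher calls, 81 had over 90% of their normalised counts in morpholino replicate 1 alone, as that explanation predicts. It does not cover the 28 lower calls, of which 24 were called again without that library; there, 118 of the 155 calls had 0 counts in both remaining morpholino libraries. As many DESeq2 calls came from 7 of the 10 splits, up to 228, as many lists from 7 splits, up to 22 against the real 12, and as many edgeR genes, past either limit, and chromosomes from all 10 splits, at 0 in the real and in every other split, and 10 splits are too few for a share under 0.05. No biological explanation of the calls was tested beyond the group itself, which stays open.

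Morpholino replicate 1 had counts in 10821 rows, and a lower depth could account for a low number. The other 5 libraries, thinned at random to its total of 1629804 counts in 20 draws each, had counts in at least 18896 rows, which argues against depth as the whole cause. In this library 1723 rows with a median of at least 10 CPM over the other 5 libraries had 0 counts, against 3 to 69 such rows in each of the others. Fewer starting cells or molecules would also leave transcripts out, and this was not tested. Rows with at least 20 counts in 1 library and 0 in the other 5 numbered 1284, 651 and 752 in control replicates 1 to 3 and 179, 750 and 1754 in morpholino replicates 1 to 3. This limit is in raw counts and asks for a higher level in the shallow morpholino replicate 1, so its 179 rows do not compare with the others.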
